A study of Macaca fascicularis with 20 samples.

How the data were processed

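The study sorted 4 NK subsets and B cells from thawed spleen cells of cynomolgus macaques and profiled them unstimulated, on 20 one-colour arrays of a custom Agilent design. Per the labels, 50 ng of total RNA was amplified by isothermal linear whole-transcriptome amplification and 400 ng of the product was labelled with Cy3. Arrays stood on 3 slides scanned on 2 days. The first slide held replicates 1 and 2 of every NK subset. The second held replicate 3 of every NK subset, replicate 4 of double-low cells and CD27 single positives, and both B cell arrays, and the third held replicates 4 and 5 of the CD11b+ subsets.

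Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.7.1.1 and handled in Partek, whose version and settings are not given in the sources used here. Per the file headers, the processed signal of each array is an intensity after background subtraction and detrending within the array, and the spot and local background medians are raw intensity. The deposited matrix holds log2 values that share 1 set of quantiles across arrays; these values were used as an alternative only.

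Of 58839 spots per array that were not controls, representing 58659 probes, those marked as non-uniform or population outliers were removed and spots of 1 probe averaged. The files name probes by transcript accession. These were matched, without version suffix, to the RefSeq gene table of the species. A total of 20417 probes (34.8%) matched 12530 genes, and the other 38242 entered only the alternative that tests every probe. A probe was tested if well above background on at least 4 of the 18 NK arrays, or 2 of the 20 arrays for the B cell comparison, and the probe of highest mean signal stood for its gene. The log2 processed signal minus the 75th percentile of its array was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), without a block, and p was adjusted by the Benjamini-Hochberg method at 0.05. The 18 NK arrays shared 1 estimate of spread, and all 20 arrays entered the B cell comparison, where the mean of the 4 NK subset means was set against B cells. Errors of differences are limma standard errors. Where no array of a group held a probe well above background, a bound against the background level is given instead of a fold.

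Choices of design, gene lists, named genes and alternatives were made before the data were examined, except those said to be added. The rule for named genes took the sort and gating markers, the 10 of largest change in each direction past the threshold, or, where none passed, the 5 of lowest p in each direction as values (10 of lowest adjusted p for the interaction), and 2 to 4 members per list. Some genes that this rule took are not reported here. The 28 lists covered sort markers, gating markers, cytotoxic granules, mature effector NK, immature or CD56bright-like NK, activating receptors, inhibitory receptors, chemokine and adhesion receptors, chemokines and cytokines, cytokine receptors, NK transcription factors, tissue residency, cell cycle, interferon response, immediate early genes, heat shock, glycolysis, apoptosis regulators, B cell, plasma cell, T cell, monocyte, dendritic cell, other innate lymphoid cell, neutrophil, erythroid, platelet and splenic stroma. Of their 407 genes 265 had a matched probe. The 26 lists with at least 3 measured members were tested with limma's camera. It was run at a preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over lists within a comparison. A list score is the mean over members of the log2 level centred on the NK arrays, compared between groups by a two-sided exact permutation test. The score does not remove a shift of all genes between arrays. For the position, the 100 genes most raised and 100 most lowered between the single positives were chosen on 1 set of replicates (1 and 2, or 3 and above) and scored on the other. The planned permutation of the scaled positions is not given, because scaling fixes the mean of both ends. Labels were exchanged before the genes were chosen instead.

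Tests on simulated data, made by adding differences to residuals shuffled between arrays, recovered 2.2% of genes changed 2-fold between the single positives, 27.4% at 4-fold, 63.4% at 8-fold and 79.4% at 16-fold. Between CD11b single positives and double-low cells they recovered 1.8%, 23.6%, 60.4% and 84.0%, and between NK and B cells 2.4%, 15.8%, 54.6% and 76.2%. In these comparisons 7, 5.2 and 10.3 unchanged genes per draw were called on average, with 50 changed genes at each of the 4 folds. With no change added, camera with the preset correlation called at least 1 list in 31 of 50 draws, and with an estimated correlation in 3 of 50. A list raised by a log2 of 1 was called in 44 of 50 draws with the preset correlation. A simulated position of 0.5 was recovered as a median of 0.504 over 20 draws. The differences simulated between the ends were not scaled to those of the data, so recovery at the size of the data was not tested.

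Alternatives fixed beforehand were quantile normalization, normexp background correction with an offset of 50 and quantile normalization, the deposited log2 values, no filter or a stricter filter on dim probes, slide as a block, the first slide alone, the replicate number or the donor label as a block, only the groups compared, every probe, the estimated correlation and each array left out in turn. Added after seeing the data were array weights (also on quantile-normalized values), array signal as a covariate, the second slide alone for NK against B cells, leaving out the 2 dimmest arrays, leaving out the 2 CD27lo arrays of highest CD27 level, and the exchange of labels for the position.

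The data differed from the plan in a few points. The files hold no gene name column, so probes were named by the match above, and normexp used the median signal. ITGAM, KLRC1, CD8A and KLRF1 had no matched probe, and of the gating markers only CD3D did. Genomic positions and unmatched probes were not analysed here. Other software was jsonlite 2.0.0 and data.table (1.17.8) in R, and Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.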

Results

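Gene expression was measured in natural killer (NK) cells and B cells sorted from the spleens of cynomolgus macaques (Macaca fascicularis). The NK cells, gated as NKG2A+ and CD8a+ without lineage markers, were divided by surface CD27, a receptor of the tumour necrosis factor receptor family, and CD11b, an integrin subunit. The 4 NK subsets were CD27lo CD11blo (double-low cells, 4 arrays), CD27+ CD11blo (CD27 single positives, 4 arrays), CD27+ CD11b+ (double positives, 5 arrays) and CD27lo CD11b+ (CD11b single positives, 5 arrays). B cells gave 2 arrays. Each array held RNA of 1 sort, labelled with 1 dye, and the number of arrays limits the precision. The 75th percentile of signal lay between 180 and 1897 units of intensity over the 20 arrays, with a median of 1280. Between 67.9% and 96.0% of probes were well above background. Double-positive replicate 4 (180 units) and double-low replicate 4 (199.6 units) were the dimmest, and the next array stood at 578.2 units. The first principal component of the 18 NK arrays held 28.2% of the variance, of which subset accounted for 32.6% and slide for 12.6%. Of the second (12.9% of the variance) slide accounted for 68.1% and subset for 21.1%, and of the third (9.68%) for 22.2% and 9.38%. A donor label, inferred from origin, sex, age and number, accounted for 77.8% of the second and 65.5% of the third. Donor label and slide overlapped. Among NK arrays the label of age 5 years occurred only in the CD11b+ subsets. The first followed array signal (Pearson r = 0.71, permutation p = 0.00015; Spearman rho = 0.75, permutation p = 0.00045; n = 18 arrays). Without the 2 arrays of most extreme signal r was 0.71. It was 0.91 within the first slide (8 arrays) and 0.69 within the second (6 arrays). The third slide held 4 arrays, too few for a value. On the first slide every CD27+ array had more signal (1313.5 units or more) than every CD27lo array (1060.6 or less). The component was likewise 57.6 or more in the former and 12.4 or less in the latter. The value of 0.91 therefore does not tell signal from CD27 status.

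NK cells were compared with B cells to see which transcripts marked the sorted NK lineage. Cytotoxic genes were higher in NK cells. EOMES, a T-box factor of NK and memory T cells, differed by a log2 of 7.31 ± 0.84 (SE; 18 NK and 2 B cell arrays; limma adjusted p = 3.01e-05). KLRD1, which encodes CD94, the partner chain of NKG2A, was higher by a log2 of 6.67 ± 0.57 (adjusted p = 7.72e-07), and HOPX, a homeodomain cofactor, by 6.55 ± 0.50 (adjusted p = 2.11e-07). Granzyme genes rose together, GZMH by 6.46 ± 0.88, GZMK by 6.08 ± 0.73 and GZMA by 6.18 ± 1.40. So did the adhesion receptor gene CRTAM (6.18 ± 0.71) and SH2D1A (6.16 ± 1.03), the adaptor of SLAM-family receptors. TRAT1, an adaptor associated with the T cell receptor, was at least 93.5-fold higher and IPCEF1 at least 29.1-fold higher, since neither B cell array held either well above background. Among the genes lower in NK cells were PADI2 (-7.51 ± 1.24), PNOC (-7.48 ± 1.32), TBC1D9 (-7.46) and LMO2 (-7.33 ± 0.86). The B cell surface genes FCRL1 (-7.09 ± 1.15) and CR2, which encodes CD21 (-6.83 ± 1.16), were lower too, as were the NADPH oxidase gene CYBB (-6.62 ± 1.43), SLC15A2 (-6.56), CHST15 (-6.42) and SWAP70 (-6.38). For each of these 20 genes all 18 NK arrays lay on one side of both B cell arrays. The genes were picked by their difference on these same arrays, which favours such a separation. For GZMA it was slight, with double-positive replicate 4 at -2.99 and B cell replicate 2 at -3.01.

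In total 362 of 12389 genes passed, 213 higher and 149 lower in NK cells, and 2806 had an unadjusted p under 0.05 where chance gives 619. All NK arrays lay above both B cell arrays for 194 of the 213, and below both for 142 of the 149. The median of all genes was shifted by a log2 of 0.36 toward NK cells, and every gene counted as higher exceeded that shift. The split depended on scaling, with 89 higher and 163 lower after quantile normalization, and 57 higher and 237 lower after normexp background correction. Both B cell arrays came from the second slide, and fitting the arrays of that slide alone gave 1926 genes. Leaving out either B cell array left 64 genes. Without replicate 1, 9 of the 20 named genes no longer passed (IPCEF1, GZMA, PADI2, PNOC, TBC1D9, FCRL1, CR2, CYBB and SWAP70; adjusted p from 0.0616 to 0.349). Without replicate 2 these and SH2D1A, 10 in all, did not pass (0.065 to 0.307). Leaving out CD11b single-positive replicate 4 gave 719 genes.

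**Figure D1:**
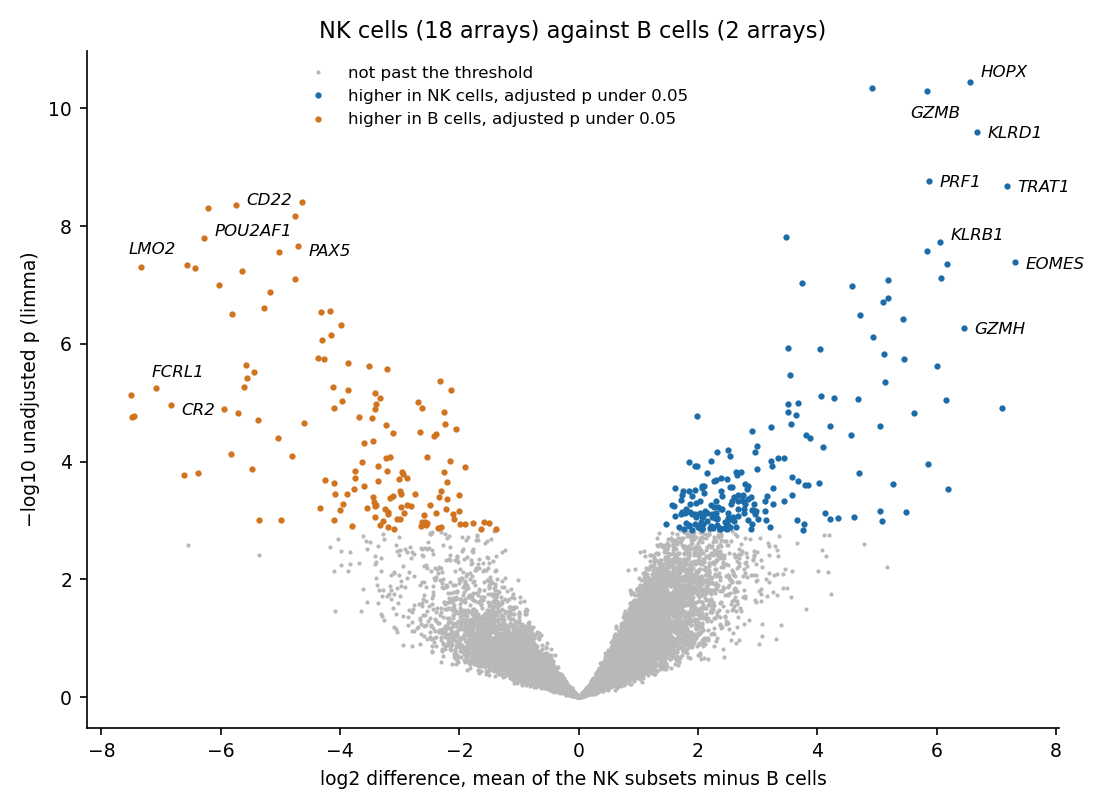
Log2 difference of each gene between the mean of the 4 NK subsets and B cells (horizontal axis) against the negative log10 of limma's unadjusted p (vertical axis), 1 point per gene. The 213 genes higher in NK cells include GZMH, PRF1 and EOMES, and the 149 genes higher in B cells include PAX5, CD22 and CR2.

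Of the 26 gene lists fixed beforehand, 9 passed limma's camera test between NK and B cells. The cytotoxic granule list stood furthest apart, with a median log2 of 5.44 (camera adjusted p = 1.48e-15). Of its 11 members 9 passed over all genes and 11 when adjusted over the list alone, among them GZMB (5.84 ± 0.46) and PRF1, which encodes perforin (5.87 ± 0.56), and none went the other way. Activating receptors and adaptors had a median of 2.70 (6 of 12 passed, all higher; 8 adjusted over the list alone, 7 of them higher). They included CD247 (6.0 ± 0.91), the zeta signalling chain, and TYROBP (3.74 ± 0.46), which encodes DAP12. Mature effector genes had a median of 1.82 (3 of 16 passed; 9 adjusted over the list alone). Of the 9, 8 were higher and 1 lower, the egress receptor gene S1PR1 at -2.04 ± 0.63. Inhibitory receptors had a median of 1.32 (1 of 5, KLRB1, at 6.06 ± 0.66; 2 adjusted over the list alone). T cell genes had a median of 1.90 (1 of 8 passed, TRAT1; 4 adjusted over the list alone). CD3D, a chain of the CD3 complex on which cells were gated out, stood at 2.50 ± 0.85 (adjusted p = 0.107; above both B cell arrays in 17 of 18 NK arrays). B cell genes fell with a median of -4.71 (8 of 11 passed; 11 adjusted over the list alone), including the lineage factor gene PAX5 (-4.71 ± 0.52) and the inhibitory receptor gene CD22 (-5.74 ± 0.58). Plasma cell genes had a median of -2.84 (1 of 6, POU2AF1, a coactivator, at -6.28 ± 0.69; 4 adjusted over the list alone). These 7 lists also passed with an estimated correlation, at adjusted p between 0.000302 and 0.0232. Cell cycle genes (median -0.84, 13 of 14 negative, 0 passed over all genes or adjusted over the list alone) had adjusted p = 0.277 with an estimated correlation. Other innate lymphoid genes (median 1.01, 1 of 10 passed, GATA3 at 5.11 ± 0.65; 4 adjusted over the list alone) had adjusted p = 0.145 with an estimated correlation. Without B cell replicate 1 the cell cycle median was 0.08 (adjusted p = 0.413; -1.59 without replicate 2) and the innate lymphoid list had adjusted p = 0.0603, and CD247 did not pass (0.0616). Without replicate 2 FCRLA, a B cell gene at -4.27 ± 0.64, did not pass (0.102). The KLRG1 receptor gene belongs to both the mature effector and the inhibitory list, and GZMB, GZMH and PRF1 belong to both the cytotoxic and the mature effector list.

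The sorted markers could be followed in part. CD27 was the only marker of the subset sort with a matched probe; CD11b (ITGAM), NKG2A (KLRC1), CD8a (CD8A) and NKp80 (KLRF1) had none. The mean CD27 level (log2, array scaled) was 4.32 ± 0.56 in CD27 single positives (SD, n = 4), 3.85 ± 0.24 in double positives (n = 5), 3.27 ± 1.13 in double-low cells (n = 4) and 3.17 ± 0.45 in CD11b single positives (n = 5). The 9 CD27+ arrays spanned 3.66 to 4.87. Of the CD27lo arrays 7 lay between 2.31 and 3.20, below all of these, while double-low replicate 4 (4.88) and CD11b single-positive replicate 4 (3.83) did not. CD3D was 0.78 ± 1.16, 1.34 ± 1.24, 0.19 ± 1.06 and 0.71 ± 1.5 in double-low cells, CD27 single positives, double positives and CD11b single positives (SD; n = 4, 4, 5 and 5). It passed between no pair. Between NK and B cells CD27 differed by 1.38 ± 0.47 (adjusted p = 0.107; above both B cell arrays in 16 of 18 NK arrays).

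The CD11b single positives were set against the CD27 single positives as the ends of the CD27 and CD11b sort. Tissue residency genes were lower in CD11b single positives: 9 of 10 members were negative, with a median log2 of -1.05 (camera adjusted p = 2.03e-05, and adjusted p = 0.0049 with an estimated correlation). All 5 arrays of CD11b single positives scored below all 4 of CD27 single positives (exact permutation p = 0.00794, the smallest that 5 against 4 arrays can give). Adjusted over the list alone 3 members were lower, RGS2 by a log2 of -2.80 ± 0.70 and RGS1 by -1.89 ± 0.59 (SE), both regulators of G protein signalling, and CRTAM by -2.58 ± 0.66. CD69, which holds lymphocytes in tissue, stood at -1.22 ± 0.58 and did not pass. Immediate early genes, induced within minutes of stimulation, had a median of -1.27 with 18 of 20 members negative (camera adjusted p = 5.16e-08; adjusted p = 0.211 with an estimated correlation). NR4A2 (-2.61 ± 0.77) and ZFP36 (-1.33 ± 0.40) were lower adjusted over the list alone. All 6 heat shock genes were negative, with a median of -1.20 (HSPA5 -1.41 ± 0.52, HSPH1 -1.73 ± 0.80; camera adjusted p = 0.000159; adjusted p = 0.211 with an estimated correlation). NK transcription factors had a median of -0.62, with 14 of 20 negative (TOX -2.41 ± 0.72, IRF8 -2.22 ± 0.71; camera adjusted p = 0.0133; adjusted p = 0.231 with an estimated correlation). Leaving out CD11b single-positive replicate 1 moved the medians to -0.66 for residency, -0.78 for heat shock genes and -0.39 for NK transcription factors, and leaving out replicate 5 moved the last to -0.29.

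The exact p of these scores was 0.0794 for immediate early genes, 0.119 for heat shock genes and 0.151 for NK transcription factors. All 5 CD11b single-positive arrays lay below the CD27 single-positive mean for immediate early and heat shock genes, and 4 of 5 for NK transcription factors. Within the first and the second slide the median was -1.67 and -0.95 for residency (-1.5 with slide as a block) and -2.01 and -0.58 for immediate early genes (-1.36). It was -1.69 and -0.35 for heat shock genes (-1.05), and -0.35 and -0.23 for NK transcription factors (-0.46). No gene passed in limma over 12192 genes, and 644 had an unadjusted p under 0.05 where chance gives 610; array weights gave 4 genes. By lowest p the higher genes were PLEKHG3 (3.22 ± 0.58, adjusted p = 0.334), MTMR11 (2.53 ± 0.49), SENP5 (at least 3.23-fold), the selectin ligand gene SELPLG (2.21 ± 0.53) and COL11A1 (3.41 ± 0.83). The lower ones included DUSP5 (-1.61 ± 0.36), NONO (-1.74 ± 0.40), the survival gene BCL2A1 (-3.43 ± 0.82) and CTNNA1 (-2.08 ± 0.51). PRF1 stood at 1.51 ± 0.44 and passed only when adjusted over the cytotoxic list alone. CD27 was at -1.15 ± 0.43 (adjusted p = 0.812). The median of all genes was 0.19. Without CD11b single-positive replicate 5 PLEKHG3 passed (adjusted p = 0.0463). The NK transcription factor list was lost without CD11b single-positive replicate 1 (adjusted p = 0.132) or CD27 single-positive replicate 2 (0.0885). Without CD27 single-positive replicate 1, 7 lists passed.

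**Figure D2:**
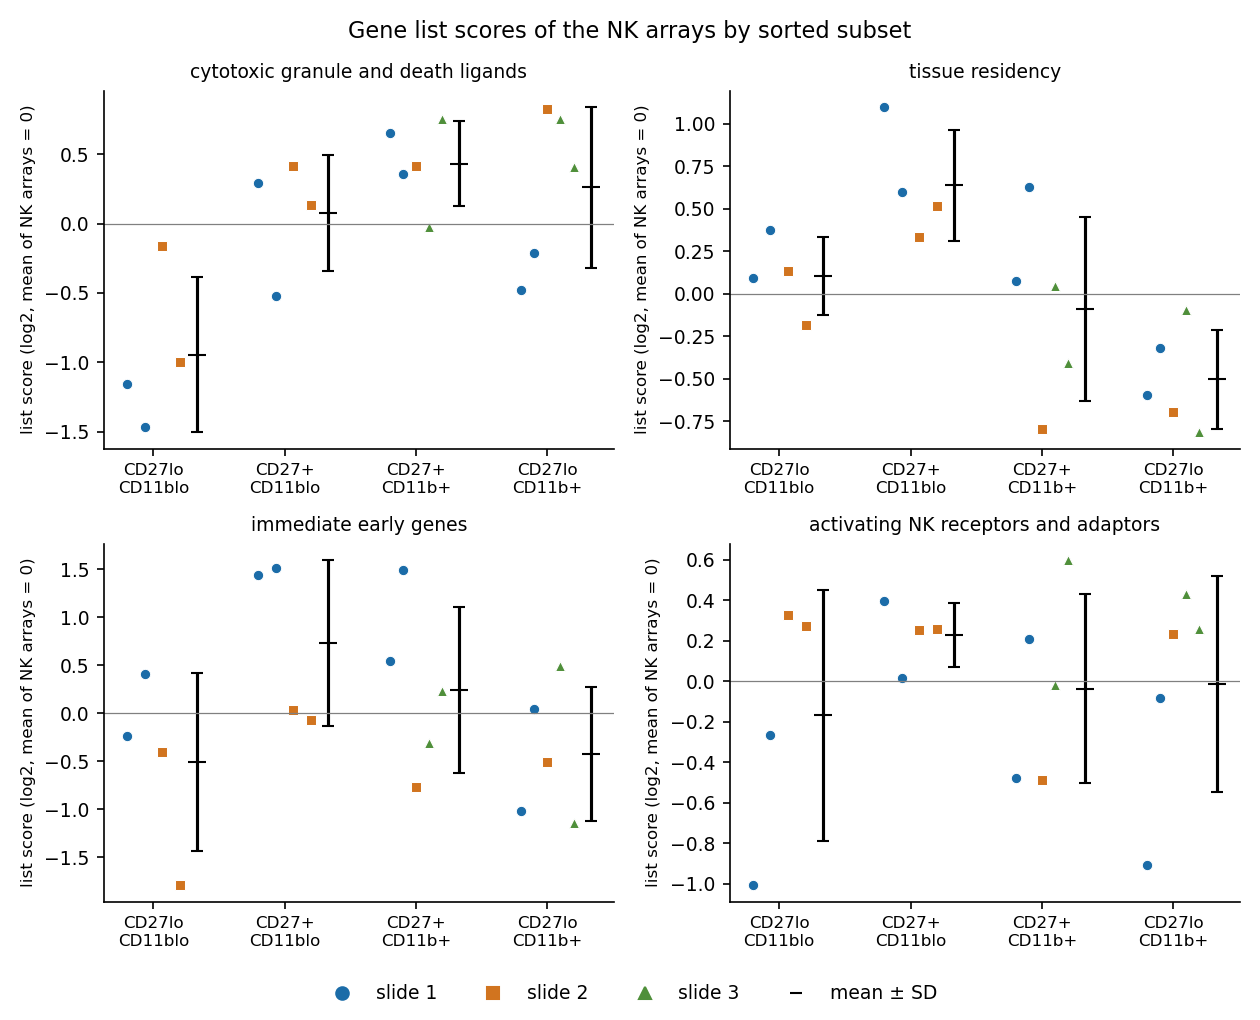
List score of each NK array (log2, vertical axis, mean of the NK arrays at 0) by sorted subset, coloured by slide, with the mean and SD of each subset as bars. For tissue residency all 5 arrays of CD27lo CD11b+ cells lay below all 4 of CD27+ CD11blo cells, and for the cytotoxic granule list all 5 arrays of double positives lay above all 4 of double-low cells.

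Double positives were compared with CD27 single positives to ask how cells that gain CD11b differ. Mature effector genes were higher in double positives, with 12 of 16 members positive and a median log2 of 0.25 (camera adjusted p = 0.0259; adjusted p = 0.129 with an estimated correlation). The leading members were GZMH (1.95 ± 0.81), FGFBP2 (1.94 ± 0.69), a protein secreted by cytotoxic lymphocytes, and PRF1 (1.33 ± 0.44). None of the 16 passed adjusted over the list alone, and 4 of 5 arrays lay above the CD27 single-positive mean (exact permutation p = 0.19). The median came close to 0 without CD27 single-positive replicate 1 (0.04) or double-positive replicate 3 (0.07), and was 0.15 and 0.17 without CD27 single-positive replicates 2 and 4. Tissue residency genes were lower, with 9 of 10 negative and a median of -0.68 (RGS1 -1.73 ± 0.59, RGS2 -1.37 ± 0.70; camera adjusted p = 0.044; adjusted p = 0.129 with an estimated correlation; 0 adjusted over the list alone). All 5 double-positive arrays scored below the CD27 single-positive mean (exact permutation p = 0.0556). Within the first and the second slide the medians were 0.21 and 0.72 for effector genes (0.39 with slide as a block) and -0.53 and -1.32 for residency (-1.13).

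No single gene passed between these subsets in limma, and 295 had an unadjusted p under 0.05; testing every probe gave 1 and array weights gave 0. PLEKHG3, a guanine nucleotide exchange factor of the actin cytoskeleton, came closest at 3.65 ± 0.58 (adjusted p = 0.0699; 5 double-positive and 4 CD27 single-positive arrays). It was followed by SENP5 (at least 3.43-fold), PDGFRB (4.67 ± 1.23), ZNF449 (3.75 ± 1.0) and SELPLG (1.97 ± 0.53). On the other side stood USP6NL (-2.85 ± 0.84), POLR2D (-2.0 ± 0.60), KIF13A (-1.59 ± 0.48), DYNLRB2 (-1.47 ± 0.45) and ANGEL1 (-1.22 ± 0.39), all with adjusted p = 1. CD27 was at -0.47 ± 0.43. PLEKHG3 passed without double-positive replicate 2 (adjusted p = 0.0287), double-positive replicate 3 (0.0395) or CD11b single-positive replicate 5 (0.0202). The effector list was lost without double-positive replicate 1 (0.164), 3 (0.0606) or 5 (0.0813) or CD27 single-positive replicate 2 (0.0984), and after quantile normalization (0.0542). The residency list was lost without double-positive replicate 1 (0.164), 3 (0.19) or 5 (0.0813), CD27 single-positive replicate 1 (0.187) or 2 (0.0574), or CD11b single-positive replicate 5 (0.0516). Leaving out 1 of the others raised the number of lists to 4 (double-positive replicate 2 or 4) or 5 (CD27 single-positive replicate 4).

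Double positives and CD11b single positives differ in the sort only by CD27. Immediate early genes were higher in double positives, with 18 of 20 positive and a median log2 of 0.60 (NR4A2 1.83 ± 0.73, ZFP36 0.84 ± 0.38; camera adjusted p = 2.43e-05; adjusted p = 0.29 with an estimated correlation). NK transcription factors had a median of 0.24 with 13 of 20 positive (IRF8, an interferon-regulatory factor, 2.15 ± 0.67; TOX 1.77 ± 0.68; camera adjusted p = 0.00901, estimated 0.29). Tissue residency genes had a median of 0.23 with 7 of 10 positive (RGS2 1.43 ± 0.66, CRTAM 1.39 ± 0.62; 0.0236, estimated 0.267), and cytokine receptors of 0.56 with 8 of 12 positive (TGFBR2 1.07 ± 0.73; 0.028, estimated 0.29). Heat shock genes had a median of 0.37 with 5 of 6 positive (HSPH1 1.12 ± 0.75; 0.0348, estimated 0.42), and apoptosis regulators of 0.07 with 9 of 15 positive (BCL2A1 1.98 ± 0.77; 0.0415, estimated 0.29). All 9 stromal and endothelial genes were negative (median -0.78; DCN, a matrix proteoglycan, at least 1.19-fold lower; PECAM1 -1.03 ± 0.50; 0.011, estimated 0.369), as were all 10 neutrophil genes (median -0.70; LTF -1.29 ± 0.86; 0.0216, estimated 0.397). None of these 8 lists passed with an estimated correlation. In no list did a member pass when adjusted over the list alone, and LTF ranged from -1.62 to -0.11 with 1 array left out in turn. Several medians rested on single arrays. For NK transcription factors it was -0.0014, 0.16, 0.49 and 0.03 without double-positive replicate 1, 2, 3 and 5, and 0.15 without CD11b single-positive replicate 5. For heat shock genes it was 0.0095 and 0.60 without CD11b single-positive replicate 1 and 4, and 0.08 without double-positive replicate 2. Without CD11b single-positive replicate 1 and double-positive replicate 2 in turn it was 0.37 and 0.34 for immediate early genes and 0.19 and 0.28 for cytokine receptors. For residency it was 0.35, 0.53 and 0.13 without double-positive replicate 1, 3 and 5, and 0.12 and 0.49 without CD11b single-positive replicate 1 and 4. For neutrophil genes it was -0.42 without double-positive replicate 5. For apoptosis regulators it was 0.13, 0.52, -0.03 and -0.08 without double-positive replicate 2, 3, 4 and 5, and 0.16, 0.25, -0.07 and -0.04 without CD11b single-positive replicate 2, 3, 4 and 5.

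In the second slide, with 1 array of each subset, 7 of the 8 medians had the opposite sign. They were -0.24 for immediate early genes, -0.25 for NK transcription factors, -0.29 for residency, -0.12 for cytokine receptors, -0.27 for heat shock, -0.74 for apoptosis and 0.21 for neutrophil genes. The stromal median kept its sign at -0.23. In the first and the third slide they were 1.66 and 0.67, 0.77 and 0.29, 0.86 and 0.18, 0.63 and 0.35, 0.93 and 0.13, 0.50 and 0.74, -0.69 and -1.11, and -1.46 and -0.49 in the same order. Both subsets held the same number of arrays on each slide, so slide as a block could not change these medians and says nothing about slide. After quantile normalization or normexp only the immediate early list passed. Without CD11b single-positive replicate 1 or double-positive replicate 2 the number of lists was 3, and without double-positive replicate 5 it was 5. The adjusted p without either of the former was 0.0957 and 0.0583 for NK transcription factors, 0.111 and 0.153 for residency, 0.207 and 0.172 for cytokine receptors, 0.445 and 0.268 for heat shock and 0.125 and 0.153 for apoptosis. Cytokine receptors were also lost without double-positive replicate 3 (0.0548) or 5 (0.054), and heat shock genes without CD11b single-positive replicate 5 (0.135) or the 2 dimmest arrays (0.0524). Neutrophil genes were lost without CD11b single-positive replicate 5 (0.157) or double-positive replicate 5 (0.186). Apoptosis genes were lost without double-positive replicate 1 (0.0553) or 5 (0.344), CD27 single-positive replicate 4 (0.0508) or CD11b single-positive replicate 5 (0.103). Without the 2 dimmest arrays the apoptosis median was -0.03.

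No gene passed between double positives and CD11b single positives in limma, and 723 had an unadjusted p under 0.05; array weights gave 0. By lowest p (adjusted p = 0.783) these were the splicing genes SRSF6 (1.32 ± 0.35) and SF3A1 (2.37 ± 0.65), PLAC8 (2.59 ± 0.71), PLEKHF2 (2.1 ± 0.58) and ZNF256 (1.93 ± 0.54). Lower in double positives were SLC5A6, a vitamin transporter (-2.09 ± 0.55), MYBBP1A (-1.36 ± 0.37), LINGO4 (-1.32 ± 0.36), TLX1 (at least 2.35-fold lower) and ASTN1 (at least 2.26-fold lower). CD27 was at 0.68 ± 0.41, and the median of all genes was -0.27.

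Cytotoxic transcripts were lowest in the double-low arrays. All 10 lists of other cell types scored higher there than in the other NK arrays, from 0.119 for T cell to 0.943 for stromal genes, and the median of all genes by 0.328, with T cell genes below that shift. The mean of the 10 lists exceeded it by 0.226 (exact permutation p = 0.0801), and a lower share of NK cells in that sort was not excluded. The PRF1 level (log2, array scaled) was 0.97 ± 0.40 in double-low cells (SD, n = 4), 2.03 ± 0.78 in CD27 single positives (n = 4), 3.36 ± 0.51 in double positives (n = 5) and 3.54 ± 0.78 in CD11b single positives (n = 5). GZMH followed with 1.01 ± 1.58, 2.95 ± 0.93, 4.90 ± 1.06 and 4.23 ± 1.62. Against double-low cells the cytotoxic granule list was higher in double positives by a median log2 of 1.02, with 11 of 11 members positive (camera adjusted p = 2.18e-06; adjusted p = 0.0327 with an estimated correlation). All 5 double-positive arrays scored above all 4 double-low arrays (exact permutation p = 0.00794). Adjusted over the list alone 4 members were higher, PRF1 (2.39 ± 0.44), GZMH (3.89 ± 0.81), NKG7, a granule membrane protein (2.28 ± 0.67), and CST7 (1.66 ± 0.63). None passed over all genes. In CD11b single positives the list was higher by 1.01 with 10 of 11 positive (camera adjusted p = 2.26e-07; adjusted p = 0.0183 with an estimated correlation; exact permutation p = 0.0397). All 5 of its arrays lay above the double-low mean, and PRF1 (2.56 ± 0.44) and GZMH (3.22 ± 0.81) were higher when adjusted over the list alone. In double-low cells against CD27 single positives all 11 members were negative, with a median of -1.09 (GZMK -1.67 ± 0.70, NKG7 -1.52 ± 0.70; camera adjusted p = 0.000483; adjusted p = 0.179 with an estimated correlation). All 4 double-low arrays lay below the CD27 single-positive mean (exact permutation p = 0.0571). Within the first and the second slide the medians were 1.84 and 1.55 (1.37 with slide as a block) for double positives, 0.86 and 1.23 (0.85) for CD11b single positives. They were -1.36 and -0.89 (-1.09, which the block could not change at equal numbers per slide) for double-low cells against CD27 single positives. Without double-low replicate 2 the median was 0.65 for CD11b single positives and -0.72 for double-low cells against CD27 single positives. Without the 2 dimmest arrays the call for double positives had adjusted p = 0.108 with an estimated correlation and a median of 1.37.

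**Figure D3:**
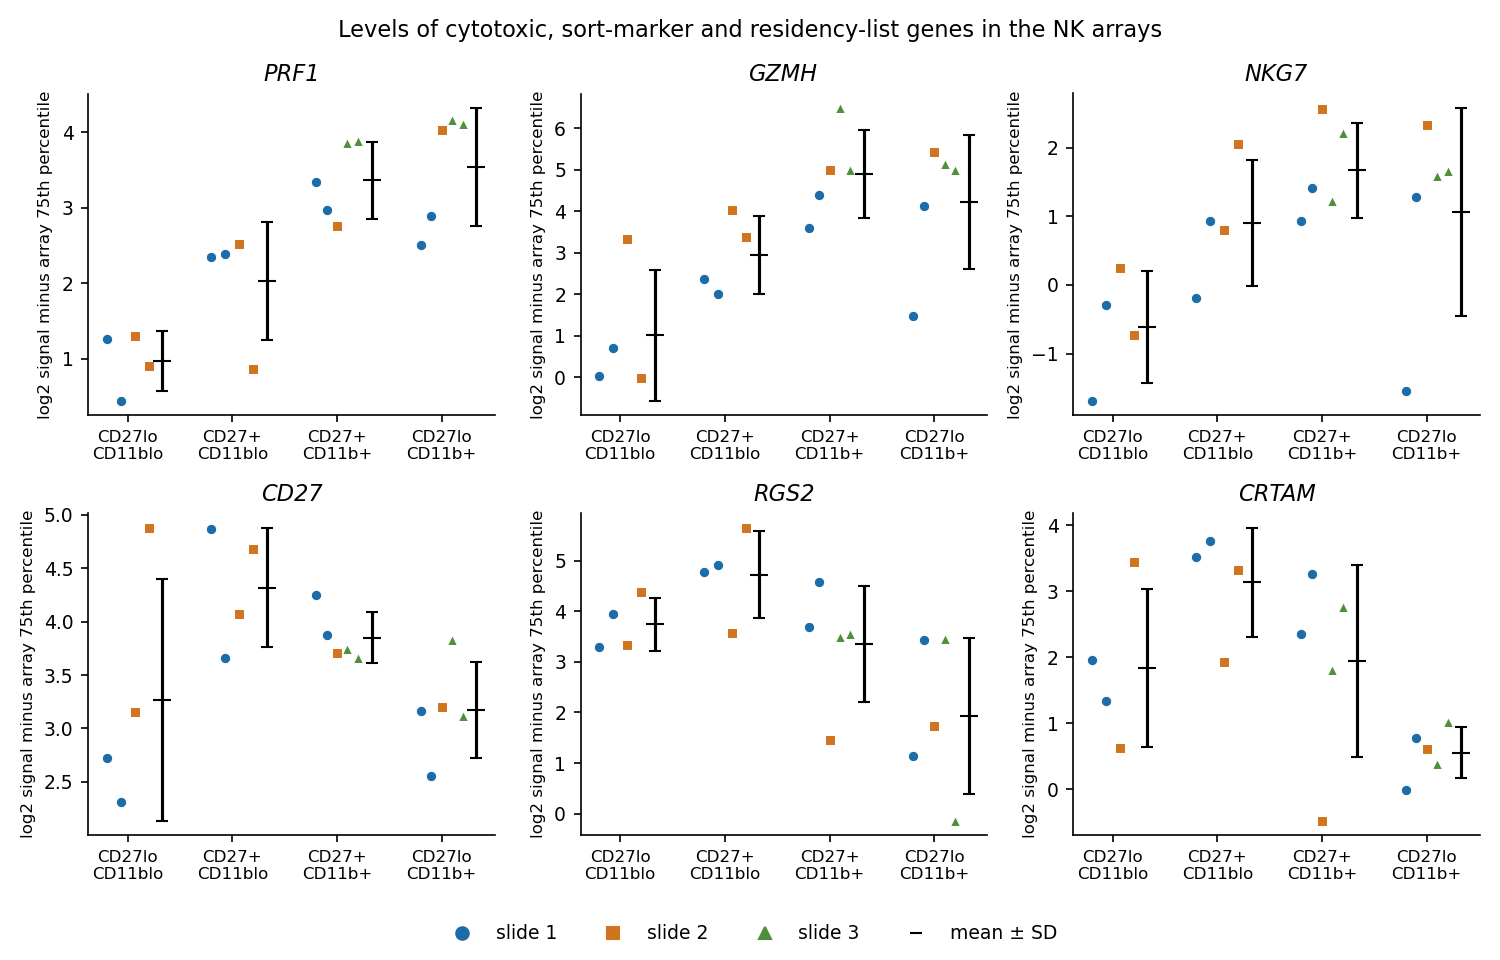
Level of 6 genes in each NK array (log2 signal minus the 75th percentile of the array, vertical axes) by sorted subset, coloured by slide, with the mean and SD as bars. PRF1 averaged 0.97 in CD27lo CD11blo cells and 3.54 in CD27lo CD11b+ cells, and CD27 in replicate 4 of the CD27lo CD11blo subset was 4.88.

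The other lists that set the double-low cells apart were less even. Against CD27 single positives NK transcription factors were lower (median -0.82, 15 of 20 negative; PRDM1 -2.47 ± 1.05, IRF8 -1.79 ± 0.75; camera adjusted p = 0.00121; adjusted p = 0.179 with an estimated correlation). Apoptosis regulators were lower too (median -0.64, 11 of 15 negative; BCL2A1 -1.90 ± 0.86; 0.0212; adjusted p = 0.179 with an estimated correlation). In both scores all 4 double-low arrays lay below all 4 others (exact permutation p = 0.0286, the smallest possible). Immediate early genes followed (median -1.34, 19 of 20 negative; PPP1R15A -2.99 ± 1.08, KLF6 -1.93 ± 0.67; 2.33e-06; adjusted p = 0.197 with an estimated correlation), as did heat shock genes (median -1.19, 6 of 6 negative; 0.0032; adjusted p = 0.265 with an estimated correlation). Without double-low replicate 4, a dim array, these medians were -0.73 and -0.66. Their scores had exact permutation p = 0.143 and 0.0857, with all 4 arrays below the CD27 single-positive mean. With 1 array left out in turn PPP1R15A ranged from -3.76 to -1.34 and KLF6 from -2.59 to -1.03. In double positives against double-low cells the NK transcription factors were higher (median 0.46, 14 of 20 positive; camera adjusted p = 0.00231; adjusted p = 0.253 with an estimated correlation). Its median was 0.08, 0.73, 0.74 and 0.28 without double-positive replicate 2, 3, 4 and 5. RUNX3 (1.76 ± 0.47), a factor of cytotoxic lymphocytes, passed when adjusted over the list alone. Immediate early genes were also higher (median 0.61, 16 of 20 positive; 0.000642; adjusted p = 0.386 with an estimated correlation), with a median of 0.23 without double-positive replicate 2 and 0.26 without double-low replicate 4. All 9 stromal and endothelial genes were lower in double positives than in double-low cells (median -1.44; camera adjusted p = 0.00538; adjusted p = 0.386 with an estimated correlation). Adjusted over the list alone 5 were lower, among them the endothelial genes PECAM1 (-1.44 ± 0.53) and CDH5 (-1.40 ± 0.47). All 5 double-positive arrays lay below the double-low mean and below all 4 arrays (exact permutation p = 0.0159). This score includes the shift of all genes in this pair, whose median was -0.47. For CD11b single positives against double-low cells the mature effector list passed with members on both sides (median 0.24, mean 0.56, 8 of 16 positive; camera adjusted p = 0.00521; adjusted p = 0.0826 with an estimated correlation). PRF1 and GZMH, which belong to the cytotoxic list too, passed there when adjusted over the list alone, and 4 of 5 CD11b single-positive arrays lay above the double-low mean (exact permutation p = 0.0794). The median was 0.38, -0.04 and 0.09 without double-low replicate 1, 2 and 4, and 0.0034 without CD11b single-positive replicate 4.

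Double-low replicate 4 had the CD27 level of CD27+ cells and was 1 of the 2 dimmest arrays. Without the 2 dimmest arrays 8 lists passed against CD27 single positives instead of 5, and 7 against double positives instead of 4. Within the first and the second slide the medians against CD27 single positives were -1.13 and -0.40 for NK transcription factors, -0.76 and -0.01 for apoptosis regulators, -1.52 and -0.98 for immediate early genes and -1.43 and -0.99 for heat shock genes. These 2 subsets held the same number of arrays on each slide, so slide as a block could not change the pooled medians. For double positives against double-low cells they were 1.17 and -0.18 (0.46 with slide as a block) for NK transcription factors, 1.02 and -0.24 (0.58) for immediate early genes and -1.56 and -0.24 (-1.11) for stromal genes. For the mature effector list of CD11b single positives they were 0.50 and 0.47 (0.31). Without double-low replicate 1 (0.0535) or CD27 single-positive replicate 4 (0.0669) the apoptosis list was lost. Without double-low replicate 2 the mature effector list was lost (median -0.04, adjusted p = 0.12), leaving 1 list between CD11b single positives and double-low cells. That number was 4 without CD11b single-positive replicate 4. For double positives against double-low cells it was 7 without double-low replicate 3 and 9 without replicate 4.

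No gene passed in limma in any comparison with double-low cells. Against CD27 single positives 1566 of 12192 genes had an unadjusted p under 0.05, where chance gives 610. There were 438 for CD11b single positives against double-low cells and 2563 for double positives against double-low cells. Array weights gave 40, 1 and 3745 genes. The median of all genes was 0.45, -0.20 and -0.47 in these comparisons. In double-low cells against CD27 single positives the lowest p belonged to POLR2M (-3.06 ± 0.54, adjusted p = 0.249), NEDD9, an adhesion scaffold (-2.67 ± 0.62), GMPS (-2.25 ± 0.53), SEC61A1, a subunit of the translocon (-2.91 ± 0.70), and PBXIP1 (-1.95 ± 0.47). The higher side included CLCC1 (at least 1.98-fold), GPR26 (2.85 ± 0.75), the amino acid oxidase gene IL4I1 (1.66 ± 0.45) and MTMR11 (1.87 ± 0.51). CD27 stood at -1.05 ± 0.46 (adjusted p = 0.374).

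For CD11b single positives against double-low cells PRF1 came first (2.56 ± 0.44, adjusted p = 0.153, all 5 arrays above all 4), then GRK5, a receptor kinase (3.30 ± 0.72), PLEKHG3 (2.49 ± 0.58), GTF2E1 (2.77 ± 0.66) and STK38 (2.51 ± 0.60). Lower were NPPC (-2.13 ± 0.57), SLC36A3 (-2.08 ± 0.58), PLEKHA6 (-2.37 ± 0.70), EPS8 (-2.41 ± 0.71) and HOOK1 (-1.34 ± 0.40), and CD27 was at -0.10 ± 0.43. For double positives against double-low cells POLR2M came first (3.20 ± 0.51, adjusted p = 0.0741), with PRF1, the small GTPase gene RAP2B (2.33 ± 0.43), PLEKHG3 (2.93 ± 0.58) and PBXIP1 (2.2 ± 0.45). Lower were ANGEL1 (-1.93 ± 0.39), XKR7 (-2.68 ± 0.58), the growth factor gene ANGPT1 (-3.39 ± 0.74), FRAS1 (at least 2.57-fold lower) and KRT25 (at least 3.35-fold lower). CD27 was at 0.58 ± 0.43, and from 0.26 to 1.12 with 1 array left out in turn. POLR2M passed without double-low replicate 3 (adjusted p = 0.025), double-positive replicate 3 (0.0373, with 4 genes in all) or CD11b single-positive replicate 5 (0.0417).

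Whether the CD11b difference depended on CD27 was asked with an interaction term. No gene passed in limma, with 175 of 12192 at an unadjusted p under 0.05, and array weights gave 0. The 10 genes of lowest p had adjusted p = 1. They included SLC17A5 (3.19), ACTRT3 (3.90), CHIC1 (3.34), CLCC1 and SLC44A4 (1.82) on the positive side and NUS1 (-4.21), PFDN4 (-3.98), ABHD1 (-3.22) and POLR2D (-2.67) on the negative. No value is given for CLCC1, since no CD27 single-positive array held it well above background. No list passed; the cytotoxic granule list came closest, with a median of -1.0 (camera adjusted p = 0.0604), while 3 lists passed without CD11b single-positive replicate 1, 2 without CD27 single-positive replicate 4, and 1 without double-low replicate 3 or 4, CD27 single-positive replicate 2 or 3, double-positive replicate 2 or 4, or CD11b single-positive replicate 2. The median of all genes was 0.10. Across genes, which are not independent replicates, the CD11b difference among CD27+ cells correlated with that among CD27lo cells at r = 0.15 (rho = 0.15, jackknife SE 0.29). The CD27 difference among CD11b+ cells with that among CD11blo cells at r = 0.50 (rho = 0.49, SE 0.33). At an unadjusted p under 0.05, 25 genes were higher in both CD11b differences against 2.08 for independent lists and 12 lower against 3.14. For the CD27 differences these were 90 against 14.0 and 75 against 34.7.

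The series title calls double positives mature intermediates, so each array was placed on the axis between the single positives, using genes chosen on other arrays. Double positives averaged 0.95 ± 0.68 on a scale with CD27 single positives at 0 (SD 0.23) and CD11b single positives at 1 (SD 0.66; n = 5, 4 and 5). They lay 0.95 above CD27 single positives and -0.05 from CD11b single positives. The ends of the scale are set by the arrays placed there, which narrows their spread, so differences were tested on unscaled scores, with labels exchanged within each set of replicates and the genes chosen anew. This test was added after the data were seen. Double positives scored higher than CD27 single positives by 0.965 (exact permutation p = 0.0333 over 60 relabellings, adjusted p = 0.2 over 6 comparisons) and differed from CD11b single positives by -0.113 (exact permutation p = 0.783). The single positives themselves differed by 1.08 (exact permutation p = 0.1), so no pair passed after adjustment, the ends of the axis included. All 5 double-positive arrays were above the CD27 single-positive mean, from 0.19 to 1.72. Double-low cells averaged 0.85 ± 0.79 (0.914 in score above CD27 single positives, exact permutation p = 0.0833), with replicate 4 at 2.03. CD11b single-positive replicate 4 stood at -0.08, within the range of CD27 single positives. The difference from CD27 single positives ranged from 0.52 without CD11b single-positive replicate 4 to 2.46 without CD27 single-positive replicate 4, and that from CD11b single positives from -0.48 to 1.46.

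**Figure D4:**
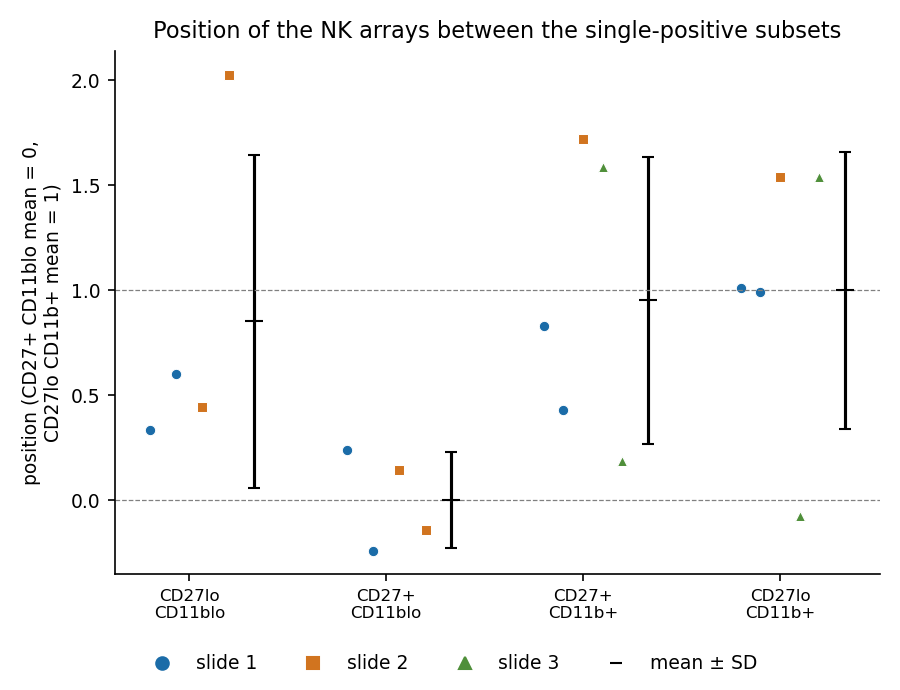
Position of each NK array (vertical axis, no unit; CD27+ CD11blo mean at 0, CD27lo CD11b+ mean at 1) by sorted subset, coloured by slide, with the mean and SD as bars. Double positives spread from 0.19 to 1.72 and CD27+ CD11blo cells from -0.24 to 0.24.

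The remaining lists passed in none of the 6 comparisons between NK subsets. Their lowest camera adjusted p was 0.0832 for glycolysis (double-low cells against CD27 single positives, median -0.62) and 0.0953 for activating receptors (the same pair, -0.61). It was 0.1 for cell cycle (double positives against double-low cells, 0.05) and erythroid genes (the same pair, -0.89). It was 0.134 for other innate lymphoid genes (double positives against CD27 single positives, -0.46) and 0.146 for immature or CD56bright-like NK genes (double positives against CD11b single positives, 0.22). It was 0.229 for monocyte genes (double-low cells against CD27 single positives, 0.63), and 0.295 for platelet and 0.371 for B cell genes (double positives against double-low cells, -0.87 and -0.62). It was 0.403 for T cell genes (CD11b against CD27 single positives, -0.38) and 0.405 for plasma and dendritic cell genes (CD11b single positives against double-low cells, -0.62 and -0.44). For interferon response it was 0.255 (the last pair, median 0.01), and for chemokine and adhesion receptors 0.326 (double positives against double-low cells, median 0.01, mean -0.04). For chemokines and cytokines it was 0.719 (CD11b against CD27 single positives, median 0.26, mean -0.03) and for inhibitory receptors 0.825 (double-low cells against CD27 single positives, 0.57).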

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

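Chosen only after the result was seen were the tests for fewer NK cells, slide, differences between animals and unequal array quality, and the counts of genes over other splits of the arrays.

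An array was singled out where it stood apart from all others of its group by more of the group's range than chance allows in about 1 of 20 groups of unrelated values. Of 12 groups of array measures 2 had such an array, of 104 groups of list scores 7 and of 208 groups of named-gene levels 11. At 1 in 20, the counts for list scores and named genes are near those of unrelated values. Any single one of these may therefore be chance. Double-positive replicate 4 had 67.9% of probes well above background, against 85.7% to 91.5% in the others of its group. Double-low replicate 4 had a position of 2.03, against 0.34 to 0.60. Its score for the immature or CD56bright-like NK list was -0.57, against 0.21 to 0.32. The chemokine and adhesion receptor score was low in replicate 1 of double-low cells (-0.32, against 0.13 to 0.18), of double positives (-0.94, against 0.09 to 0.32) and of CD11b single positives (-0.40, against 0.20 to 0.34). These arrays shared the first slide, the donor label and an age of 4 years. Replicate 2 of each of these subsets, also on the first slide, was not set apart. The heat shock score was 1.27 in double-positive replicate 2, against -0.46 to -0.12. The monocyte score was 0.25 in CD27 single-positive replicate 3, against -0.34 to -0.28, and the platelet score was -0.88 in CD27 single-positive replicate 2, against -0.04 to 0.07.

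Single genes stood apart in the same way. In CD27 single positives these were COL11A1 in replicate 2 (-8.08, against -5.29 to -4.83), ANGEL1 in replicate 3 (0.46, against -0.03 to 0.02), and in replicate 4 TLX1 (-6.26, against -4.39 to -4.28) and PRF1 (0.87, against 2.35 to 2.52). In double-low replicate 4 they were BCL2A1 (-0.20, against 0.76 to 0.90), ZNF256 (-2.39, against -0.97 to -0.76) and GMPS (-1.15, against 0.40 to 0.55). In CD11b single positives they were LINGO4 in replicate 2 (-0.079, against -1.37 to -1.02), GPR26 in replicate 4 (-6.62, against -4.59 to -3.81), and in replicate 5 BCL2A1 (-4.20, against -0.39 to 0.05) and POLR2M (-0.74, against 0.43 to 0.90).

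The cytotoxic granule list was lower in double-low cells than in the other NK subsets, by 1.22 in mean score (exact permutation p = 0.00131). B cells as the whole cause are argued against by the B cell list, which in the closest double-low array was -2.95 from the B cell arrays. A smaller share of B cells in the sort is not excluded by this distance. The B cell list scored 0.458 higher in double-low than in the other NK arrays (exact permutation p = 0.275). Array signal as the whole cause is argued against by a median difference of 0.68 with it as a covariate, against 1.03 without, still past the test with an estimated correlation (p = 0.00126). Fewer NK cells in the sort would lower NK receptor genes as much, and these fell by 0.22 (exact permutation p = 0.00196 for the difference of both scores), but all 10 lists of other cell types were higher in double-low cells, from 0.119 for T cell to 0.943 for stromal genes (median of all genes 0.328, above T cell genes; mean of the lists 0.226 beyond it, exact permutation p = 0.0801), so a lower share of NK cells cannot be told apart. A lower cytotoxic content of the CD27lo CD11blo cells themselves stays open beside it, untested.

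The tissue residency list was higher in CD27 than in CD11b single positives, by a median of 1.05. If the immediate early response alone raised it, members outside that response would differ little. Without CD69, RGS1, RGS2 and DUSP6 the median of the 6 remaining genes was 0.39 (ITGA1, CXCR6, CD9, CD101, CRTAM and CXCR3). RGS1 and RGS2, which are not in the immediate early list, were among the members that passed when adjusted over the list alone. Leaving them out tends to lower the median whatever the cause, so the fall does not tell whether such a response was the source. The score of these 6 still separated the arrays (exact permutation p = 0.00794), so a residency difference stays open beside such a response. CRTAM by itself gave this separation, at -0.0094 to 1.01 in CD11b and 1.92 to 3.76 in CD27 single positives. It was the only one of the 6 that passed when adjusted over the list alone. Whether the others separate the arrays without CRTAM was not tested. Array signal as a covariate left a median of 1.0 (estimated-correlation p = 0.000217) and slide as a block 1.5, with 1.67 and 0.95 within slides, which argues against both as the cause. An immediate early response may come from handling or from the cells' state in the animal, and no value here decides between these.

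No gene passed the threshold between NK subsets. Adding array signal as a covariate gave 0 genes over the 6 pairs. The simulations, run without the covariate, recovered 2.2% of 2-fold and 27.4% of 4-fold changes between the single positives. A count of 0 therefore does not decide whether an array-wide component tied to signal hid differences. Adding the donor label as a block gave 0 as well, but differences between animals cannot be told apart, because the donor label was inferred from origin, sex, age and number, and replicate 3 carries 4 ages. Arrays of unequal quality remain possible, since array weights gave 3790 genes over the 6 pairs and 655 on quantile-normalized values, nearly all between double positives and double-low cells. But 7 of 100 splits of those arrays gave as many with weights (3745 for the real groups, 4767 at most elsewhere), so chance was not excluded and quality cannot be told apart either.

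Other splits of the same arrays into groups of equal sizes were fitted for each comparison. The counts of genes were 0 for the real groups, so every split gives as many (100 of 100, or 35 of 35 for double-low cells against CD27 single positives), and nothing follows about chance. The highest other splits gave 2 genes for CD11b against CD27 single positives, 2 for double positives against CD27 single positives, 1658 for double positives against CD11b single positives, 1 for double-low cells against CD27 single positives, 9 for CD11b single positives against double-low cells, 735 for double positives against double-low cells and 3154 for the interaction. The split with 1658 genes exchanged double-positive replicate 3 and CD11b single-positive replicate 4, and that with 735 placed double-positive replicate 3 with the double-low cells. Both kept the remaining arrays in their groups. They were picked as the highest of 100 splits, and why they gave so many genes was not tested. On the first principal component, which followed array signal, double-positive replicate 3 stood at -57.1 and CD11b single-positive replicate 4 at 77.3. Double-positive replicates 1, 2, 4 and 5 stood at 92.0, 76.6, -67.0 and 101.6, and the other CD11b single positives between -77.9 and 12.4. For the lists, 3 of 100 splits gave as many for double positives against CD11b single positives (8 real, 9 at most elsewhere). Taken alone that share is low, but it is not adjusted over the 6 comparisons, and none of the 8 lists passed with an estimated correlation. It therefore does not exclude chance. Chance was not excluded for CD11b against CD27 single positives (28 of 100; 4 real, 7 elsewhere), double positives against CD27 single positives (21 of 100; 2 real, 5 elsewhere), double-low cells against CD27 single positives (4 of 35; 5 real, 5 elsewhere), CD11b single positives against double-low cells (52 of 100; 2 real, 6 elsewhere) or double positives against double-low cells (21 of 100; 4 real, 8 elsewhere).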

How the results depend on the processing

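Array weights, signal as a covariate, the second slide alone, leaving out the 2 dimmest arrays, leaving out the 2 CD27lo arrays of highest CD27 level and the exchange of labels for the position were chosen only after the data were seen. Where a value moved, the cause was not tested.

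Between NK subsets the count of genes was 0 under every alternative except array weights (4 genes for CD11b against CD27 single positives, 40 for double-low cells against CD27 single positives, 1 for CD11b single positives against double-low cells, 3745 for double positives against double-low cells), array weights on quantile-normalized values (3, 1 and 651 for the last 3 of these) and every probe (1 for double positives against CD27 single positives), arrays left out in turn aside. For NK against B cells it was 600 with slide as a block (401 higher and 199 lower; 304 of the 362 shared), 1824 over every probe, 5714 with array weights and 4941 with weights on quantile-normalized values. It was 1926 on the second slide alone (309 shared) and 590 without the 2 CD27lo arrays of highest CD27 level (359 shared).

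The number of lists rested on the correlation setting. With an estimated correlation it was 1 instead of 4 for CD11b against CD27 single positives, 0 instead of 2 for double positives against CD27 single positives, 0 instead of 8 for double positives against CD11b single positives, 0 instead of 5 for double-low cells against CD27 single positives, and 1 instead of 2 and 1 instead of 4 for CD11b single positives and double positives against double-low cells. Slide as a block gave 7 for the single positives and 1 for the interaction. Normexp gave 4 for double positives against CD27 single positives, 1 for double positives against CD11b single positives and 2 for the interaction, and quantile normalization and the deposited values gave 1 for each of the latter pair. Without the 2 dimmest arrays there were 8 for double-low cells against CD27 single positives, 7 for double positives against double-low cells and 1 for the interaction. Without the 2 CD27lo arrays of highest CD27 level there were 8, 7 and, for CD11b single positives against double-low cells, 6.

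Deviations of same-numbered arrays correlated at a median of 0.22 over 25 pairs, from -0.30, with 17 above 0.1, against a median of -0.067 and 21 of 96 above 0.1 for different donor labels. Not every pair exceeded 0.1 and no label states which arrays share an animal, so the numbers were not taken to pair the arrays. Same-numbered arrays were still more alike by these medians. Errors and p-values without a block treat all arrays as independent, and may be wrong where arrays share an animal. Donor label accounted for 77.8% of the second and 65.5% of the third principal component, and 12 of 18 arrays correlated best with an array of their own number, a hint from the data only. The replicate block by number gave 1 list for double positives against CD27 single positives and 1 for the interaction, and CD3D at 0.13 for CD11b single positives against double-low cells. The block by donor label gave 5, 1 and, for CD11b single positives against double-low cells, 4 lists, and 84 genes for NK against B cells (76 of the 362 shared), where GZMA and SWAP70 did not pass, KLRG1 reversed to -0.69 and MCM5 to 0.19. With values centred on the number the double-positive position was 0.76 above CD27 single positives. The block by either label changed no other count by over 1.5 times. Of 34 called lists 1 no longer passed with the block by number and 4 with the block by donor label.

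The position of double positives above CD27 single positives was 0.98 with no filter, 0.86 with the larger gene set, 0.79 without the 2 dimmest arrays and 0.52 without the 2 CD27lo arrays of highest CD27 level, against 0.95 as reported. The exchange of labels tested the unscaled difference of 0.965. Its distance from CD11b single positives turned positive after quantile normalization (0.11), with the deposited values (0.11) and with the smaller gene set (0.0059). The similarity across genes of the CD11b and the CD27 differences moved under no alternative by more than its error.

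Some named genes reversed. For double positives against CD11b single positives the first slide alone gave IFNGR1 -0.35 (reported 0.81), CXCR6 -0.64 (0.24) and G0S2 1.03 (-1.98), none of which had passed, and array weights CXCR6 -0.0016. For CD11b single positives against double-low cells CD27 was 0.027 with normexp, 0.0097 after quantile normalization, 0.0081 with the deposited values, 0.34 on the first slide, 0.44 without the 2 dimmest arrays, 0.28 without the 2 CD27lo arrays of highest CD27 level and 0.26 and 0.25 with the array weights, and B3GAT1 was 0.062 on the first slide. Of 3594 values of named genes under alternatives other than leaving 1 array out, 3464 kept their direction and side of the threshold, 111 newly passed, 3 no longer passed and 16 reversed. Of 306 values of called lists 252 kept them and 54 no longer passed.

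With 1 array left out in turn the count of genes ranged from 0 to 1 for CD11b single positives and for double positives against CD27 single positives, 0 to 4 for double positives against double-low cells and 64 to 719 for NK against B cells, and was 0 throughout for the other pairs. The lone B cell array was then assumed to vary like the other groups. The number of lists ranged from 3 to 7, 0 to 5, 3 to 9, 4 to 8, 1 to 4, 4 to 9, 0 to 3 and 7 to 10, in the order of CD11b against CD27 single positives, double positives against CD27 and against CD11b single positives, double-low cells against CD27 single positives, CD11b single positives and double positives against double-low cells, the interaction, and NK against B cells. The position ranged from 0.52 to 2.46 above CD27 single positives and from -0.48 to 1.46 from CD11b single positives, and the similarity from 0.0024 to 0.30 for the CD11b and from 0.34 to 0.63 for the CD27 difference. HSP90AB1 ranged from -0.015 to 0.44 (double positives against CD11b single positives), and for CD11b single positives against double-low cells CD3D ranged from -0.58 to 0.42 and CD27 from -0.42 to 0.44.

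Signal over background limits what dim probes can show, and on the dimmest array 67.9% of probes were well above it. Fitting only the groups compared equals the reported fit for NK against B cells, so it was not run there.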

Other observations

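The test of exchanged labels was chosen only after the result was seen.

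Beyond the lists that passed, NK and B cells differed in single genes of further lists. Of the immature or CD56bright-like list, 4 of 13 members passed over all genes. The growth factor gene AREG (-4.33) and the transcription factor gene BACH2 (-5.81) were lower in NK cells, with all 18 NK arrays below both B cell arrays. Over the whole list 7 members were positive and 6 negative, and it did not pass (camera adjusted p = 0.359). In double positives against double-low cells 8 of 9 measured genes of other innate lymphoid cells were negative (median log2 -0.55), and 2 passed when adjusted over the list alone. All 5 erythroid genes were negative there too (median -0.89, exact permutation p = 0.0159, 5 against 4 arrays), and 1 passed when adjusted over the list alone. The median of all genes was itself -0.47 in this pair, and these list medians and the score include that shift. Neither list passed in camera (adjusted p = 0.217 and 0.1).

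The CD27 transcript lay at 4.88 in double-low replicate 4 and at 3.83 in CD11b single-positive replicate 4, against 3.66 to 4.87 in the CD27+ arrays. If their labels had been exchanged with those of CD27+ arrays, 2 CD27+ arrays should lie at the level of CD27lo cells. The lowest CD27+ array lay 0.46 above the highest of the other CD27lo arrays (SD 0.46 among the former and 0.36 among the latter), but the 95% prediction range of the latter reached 3.83, above 4 of the 9 CD27+ arrays, so an exchange of labels cannot be told apart. The exchange of CD11b single-positive replicate 4 with double-positive replicate 3 gave the most genes of 100 splits (1658 against 0). It would leave CD27 at 3.71 in a CD27lo array, within that prediction range. The level of 3.83 would then belong to a CD27+ array, within the range of those arrays. CD27 levels therefore do not decide on this exchange. A single wrong label or a sort of lower purity may also account for either array, and neither was tested.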
